A study of Mus musculus with 12 samples.

How the data were processed

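Gene expression was measured in murine bone marrow-derived dendritic cells, which were grown from marrow with GM-CSF at 20 ng/ml and harvested on day 7 as immature cells. They were then cultured with 300 µg/ml of nanoparticles made of poly(γ-glutamic acid), a biodegradable polymer (γ-PGA), and RNA was taken after 6, 12 or 24 h. Cells labelled 0 h stand for the start of the exposure. Each of the 4 groups held 3 samples, which the series design describes as independent experiments. No untreated culture kept for 6, 12 or 24 h was among the samples, so time in culture and exposure could not be separated. Cy3-labelled cRNA was hybridised to Agilent mouse 1-colour arrays.

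The deposited files held 2 sources of values. The scanner files held the intensity of every spot, per the file headers from Agilent Feature Extraction 9.1.3.1, and their processed signal was background-subtracted and detrended by that software on a linear scale. The value table that the authors deposited held, for each probe, the linear ratio to the median of its 3 values at 0 h, with a lowest value of 0.01. Any scaling between its columns is not given in the sources used here. The genome build is not given in the sources used here either, so no coordinates are printed. Each scanner file held 45018 spots, of which 1639 were controls and 43379 were not. The non-control spots carried 41174 probes, all of them among the 41262 probes of the value table.

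The scanner values were taken as the main source before the data were examined, together with the comparisons, the gene lists, the rule for naming genes and the other settings to try. Spots marked by the software as outliers were left out, 732 in all. The log2 of each spot was taken, the 75th percentile of the array's non-control spots was subtracted, and the remaining spots of a probe were averaged. That percentile was taken before outlier spots were left out. Probes were kept where every array of at least 1 group called them well above background, which left 23496 probes. Names came from RefSeq accessions matched to a gene table of the mouse assembly GRCm38.p6, used for names only. It matched 22937 of 23837 probes with an mRNA accession and named 22951 probes, 55.7% of all. The kept probe with the highest mean stood for its gene, and a probe without a symbol counted under its own identifier. This gave 18404 genes, 11576 of them with a symbol. Of 3651 genes with several kept probes, 2, 4 and 1 had probes called in both directions at 6, 12 and 24 h against 0 h.

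Groups were compared with limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8, for reading files. A single fit of the 4 group means to all 12 arrays left 8 residual degrees of freedom and gave every contrast its standard error (SE) and two-sided p. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes and a change of at least 2-fold. A moderated F-test over the 3 contrasts with 0 h tested the time course. A gene counted as changed over it at an adjusted p under 0.05 and a change of at least 2-fold in any of these contrasts. The spread behind each p was that between 3 samples per group, and the number of arrays limits the precision. After the sources were seen to differ, the log2 ratios of the value table were fitted the same way for the same 18404 genes and are reported beside the scanner values. Contrasts within a slide that rest on 1 array of a group assume that it varies like the other groups. Between neighbouring times they equal the contrasts with the slide as a block. The 2 sources were also fitted together with a term for source, time and their interaction. That fit took every array and every table column as an independent sample, though both sources carry the labels of the same 12 samples.

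Of 30 gene lists written from textbook knowledge, 29 had at least 5 measured members and were tested. The lists hold 494 genes, of which 10 stand in 2 lists. limma's camera compared the members of a list with all other genes at a preset correlation of 0.01 between genes. Its p was adjusted over the 87 tests of 29 lists at 3 times for each source. Beside it stand camera with an estimated correlation and fry. A small p from fry says that a list's genes move, on balance, in 1 direction, without a comparison with other genes. The members called higher or lower were counted after adjustment over all genes and again adjusted over the list alone, and the numbers of members called were equal in every list. Cd40 and Il12b had no matched probe and are not analysed here.

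Genes were named by a fixed rule. For 6, 12 and 24 h against 0 h it took the 10 largest rises and the 10 largest falls past the threshold with 3 arrays on the same side of all 3 arrays at 0 h. For 12 h against 6 h and for 24 h against 12 h it took the 5 largest of each. From each list it took up to 3 members with the largest rise and up to 3 with the largest fall. Fixed markers of maturation, cytokines and Toll-like receptor signalling were to be named whatever their values. Some of their values at 12 or 24 h, among them those of Cd80 and Cd86 at 24 h, are not given. The rule was applied to the value table as well once the sources were seen to differ, and space allowed only part of the genes it gives. Some of them are not reported here for another reason than space. Where a gene was not well above background on every array of a group, or saturated on every array of a group, its scanner fold is given as at least the value at that bound. Background limited 1033, 1016 and 96 called genes at 6, 12 and 24 h against 0 h. These counts include any gene also saturated in the other group. They also include any gene below background in both groups, which has no bound.

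The steps were tested on simulated data for 6 h against 0 h with 18404 genes and 40 changed genes per fold size. From scanner values 0, 13, 37, 40 and 39 genes were called the right way at 1.5, 2, 3, 4 and 8-fold, none of these 40-gene sets had a call the wrong way, and limma made 3 calls among unchanged genes. With the spread of the value table, these were 1, 13, 37, 37 and 40, with 4 such calls. A shifted chemokine list was called from either source, and camera called 0 of the other tests out of 87. The simulated noise was independent between genes. The simulation therefore cannot show how often camera calls lists wrongly where genes vary together, as on real arrays.

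The other settings fixed in advance were normexp background correction with offset 50, quantile normalization, median scaling, the value table, no filter and a filter over all arrays, every probe or the mean of a gene's probes, the replicate number or the slide as a block, the 2 compared groups alone, a variance trend, other thresholds and leaving out each array. As the files hold no mean signal, normexp used the median signal and median local background. Alternatives for the value table were chosen after the data were seen.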

Results

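The data were 12 arrays of bone marrow-derived dendritic cells at 0, 6, 12 and 24 h of exposure to γ-PGA nanoparticles, with 3 samples per time. Between 50.9% and 59.6% of the non-control spots of an array were well above background, and 165 to 223 spots per array were saturated. The 75th percentile of the signal ranged from 338.6 to 472.3 intensity units. Outlier spots numbered 628 on the array of 6 h replicate 2 and at most 42 on any other. The arrays lay on 3 slides. The first held the 3 arrays at 0 h and 6 h replicate 1, the second held 6 h replicates 2 and 3 with 12 h replicates 1 and 2, and the third held 12 h replicate 3 with the 3 arrays at 24 h. Each slide was scanned as 1 batch, so slide and scan could not be separated. In the value table the median ratio of a column was 1 in the columns at 0 h. It was 1.026, 1.103 and 1.147 in those at 6 h, 1.334, 1.143 and 1.151 in those at 12 h, and 1.29, 0.9428 and 1.005 in those at 24 h. Up to 15 values per column stood at the lowest ratio.

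The 2 deposited sources of values were set against each other first, because they should describe the same samples. The changes of single genes at 6 h against 0 h correlated between them across 18404 genes with Pearson's r of 0.73 and Spearman's rho of 0.7. At 12 h r was 0.54 and rho 0.48, and at 24 h r was -0.08 and rho -0.06. The scanner change at 12 h correlated more highly with the table's change at 6 h, with r of 0.64, than with its change at 12 h. The scanner change at 6 h and the table's change at 12 h also gave 0.64. Genes are not independent replicates, and these values describe likeness only. Within the scanner files the arrays labelled 24 h correlated at 0.991 with those at 0 h, 0.923 with those at 6 h and 0.91 with those at 12 h, while arrays at 0 h correlated among each other at 0.995. On the log2 ratios of the value table the 24 h columns correlated at 0.896 with the 12 h columns and 0.742 with the 6 h columns, and the columns at 0 h, which hold ratios near 1, were left out of this. The deviation of a sample from its group mean correlated between the sources with r from 0 to 0.145 for the same sample. This was taken over 9017 genes with complete values and a mean scanner signal above the median. For the same array under another background correction the lowest r was 0.48. Results at 6 and 12 h are therefore given first where the sources share them, and those of arrays and columns labelled 24 h are given for each source apart. Where 2 values stand together with no source named, the first is from the scanner values and the second from the value table, and n is 3 per group throughout.

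Exposure for 6 h was compared with 0 h, to ask what the particles change early in the cells. Transcripts of inflammatory cytokines rose in both sources. Il6, whose product drives acute inflammation and T-cell help, rose 653-fold in the scanner values (log2 change 9.35 ± 0.063 SE, n = 3 per group, limma adjusted p = 2.58e-13) and 105-fold in the value table (6.71 ± 0.07). Il1a, an alarm cytokine, rose 443-fold and 61.3-fold in the same order, and Tnf, an early inflammatory mediator, 60.6-fold and 37.1-fold. Il1b, a cytokine that needs cleavage to act, rose at least 16.9-fold in the scanner values, where it saturated, and 27.5-fold in the value table. Il10, which restrains inflammation, rose at least 49.7-fold in the scanner values and 6.46-fold in the value table. The growth factors Csf2 and Csf3 rose at least 165-fold and 86-fold by the scanner and 4.78-fold and 52.1-fold by the table. Of 21 cytokine genes 18 rose and 0 fell by the scanner, and 15 rose and 1 fell by the table. Limma passed equal numbers adjusted over the list alone. The list's median log2 change was 5.46 (camera adjusted p = 1.01e-12, adjusted p = 0.188 with an estimated correlation) and 2.56 in the table (adjusted p = 4.06e-06, adjusted p = 0.618 with an estimated correlation). With members below background at their bound the scanner median was 4.73. With the slide as a block, which here compares within slide 1 alone, it was 5.54. Osm, a cytokine of the interleukin 6 family, went apart between the sources and rose 13.9-fold by the scanner while it fell by 1.78 on the log2 scale in the table.

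Chemokines that draw neutrophils rose at 6 h in both sources. Cxcl1 rose 738-fold in the scanner values (9.53 ± 0.088, n = 3 per group, adjusted p = 9.44e-13) and 407-fold in the value table (8.67 ± 0.57, adjusted p = 2.84e-07). Cxcl2 rose 158-fold and 129-fold, and Cxcl5, a further neutrophil attractant, 159-fold and 1380-fold. Cxcl3 rose at least 55.1-fold on saturated arrays and Ccl5, which draws T cells, at least 15.0-fold, against 330-fold and 17.9-fold in the table. Cxcl10, an interferon-induced T-cell attractant, rose 113-fold in the table (6.82 ± 0.077) but 1.88-fold in the scanner values, below the 2-fold threshold, which it passed with the slide as a block (log2 change 1.02). Of 20 chemokine genes 15 rose and 1 fell by the scanner (median 1.86, adjusted p = 1.62e-08, adjusted p = 0.194 with an estimated correlation). By the table, 13 rose and 1 fell (median 3.34, adjusted p = 0.000646, adjusted p = 0.618 with an estimated correlation).

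Maturation markers rose as well at 6 h. Cd83 and Cd86, surface proteins of mature dendritic cells that help activate T cells, rose 3.76-fold (1.91 ± 0.046) and 2.76-fold (1.46 ± 0.06) in the scanner values and 9.41-fold and 5.26-fold in the value table, with n = 3 per group. Ccr7, the receptor that guides mature cells to lymph nodes, rose 5.28-fold and 5.52-fold (scanner adjusted p = 8.25e-10 with limma). Fscn1, an actin-bundling protein of dendrites, rose 8.19-fold and 4.73-fold. Cd80, a further costimulatory protein, rose 7.25-fold in the scanner values (2.86 ± 0.058) and did not pass in the value table (-0.02 ± 0.12, adjusted p = 0.877). Of 16 genes of maturation and costimulation 14 rose and 1 fell by the scanner (median 2.22, adjusted p = 1.38e-07, adjusted p = 0.188 with an estimated correlation), and 11 rose and 0 fell by the table (median 1.87, adjusted p = 2.31e-05, adjusted p = 0.618 with an estimated correlation).

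Targets and feedback inhibitors of NF-kB, the transcription factor that Toll-like receptors activate, rose in 20 of 21 cases by the scanner (median 2.52, adjusted p = 1.66e-11, adjusted p = 0.194 with an estimated correlation) and in 18 of 21 by the table (median 2.62, adjusted p = 6.72e-07, adjusted p = 0.618 with an estimated correlation), and 0 fell in either. Dusp2, a phosphatase that ends kinase signals, rose 15.4-fold and 22.0-fold, and Traf1, an adaptor of TNF receptors, 7.82-fold and 20.7-fold. With the slide as a block the list's scanner median was 3.03. Among Toll-like receptors and adaptors 8 of 19 genes rose and 2 fell by the scanner (median 0.64, adjusted p = 0.0135, adjusted p = 0.649 with an estimated correlation), and 8 rose and 0 fell by the table (median 0.80, adjusted p = 0.00924, adjusted p = 0.76 with an estimated correlation). Tlr1, which pairs with Tlr2 in sensing lipopeptides, rose 5.48-fold and 15.5-fold, and Irak3, a brake on this signalling, 5.48-fold and 5.89-fold. Cd14, a co-receptor for bacterial lipids, rose at least 2.45-fold and 5.55-fold. Myd88, the shared adaptor, rose 2.51-fold by the scanner and 1.75-fold, short of the threshold, by the table. Tlr2 rose 3.64-fold by the table alone, with 1.56-fold by the scanner. Tlr4, the receptor for lipopolysaccharide, did not pass in either (0.08 ± 0.057 and -0.60 ± 0.069).

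Interferon and effector genes also rose at 6 h. Ifnb1, which encodes interferon beta, rose 8.33-fold (3.06 ± 0.07) and 37.7-fold (5.23 ± 0.12). Rsad2, an antiviral protein, rose 9.76-fold and 108-fold, Isg15, a ubiquitin-like modifier, 7.43-fold and 14.9-fold, and Gbp5, a GTPase of host defence, 14.6-fold and 11.3-fold. Of 27 type I interferon genes 15 rose and 0 fell by the scanner (median 1.04, adjusted p = 3.03e-07, adjusted p = 0.425 with an estimated correlation), and 16 rose and 1 fell by the table (median 1.17, adjusted p = 5e-05, adjusted p = 0.693 with an estimated correlation). Of 10 interferon-gamma-type GTPases 6 and 8 rose and 0 fell (medians 1.35 and 2.30, adjusted p = 0.00011 and 4.57e-05, adjusted p = 0.208 and 0.618 with an estimated correlation). Ptgs2, which makes prostaglandins, rose at least 991-fold by the scanner and 232-fold by the table, and Nos2, the inducible nitric oxide synthase, at least 12.8-fold and 7.86-fold. Saa3, an acute-phase protein, rose 143-fold and 303-fold. Of 20 effector enzymes and acute-phase products 13 rose and 5 fell by the scanner (median 2.10, adjusted p = 0.0101, adjusted p = 0.649 with an estimated correlation), and 14 rose and 4 fell by the table (median 2.01, adjusted p = 0.00871, adjusted p = 0.672 with an estimated correlation). MHC class I genes shifted up as a list (medians 0.36 and 0.70, adjusted p = 0.00928 and 0.000185, adjusted p = 0.649 and 0.668 with an estimated correlation), with 0 of 16 members past the limma threshold by the scanner and 6 by the table.

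Genes of oxidative stress, cholesterol synthesis and cell death moved in both sources at 6 h. Slc7a11, which imports cystine for glutathione, rose 11.6-fold (3.53 ± 0.071) and 52.6-fold, and Nqo1, a quinone reductase under NRF2, 6.18-fold and 43.4-fold. Of 17 oxidative stress genes 10 rose by the scanner (median 1.38, adjusted p = 1.93e-05, adjusted p = 0.471 with an estimated correlation) and 14 by the table (median 3.28, adjusted p = 4.04e-08, adjusted p = 0.618 with an estimated correlation), and 0 fell. Hsd17b7 and Hmgcs1, enzymes of cholesterol synthesis, rose 12.4-fold and 5.78-fold by the scanner and 4.46-fold and 3.24-fold by the table. Of the 20 cholesterol genes 17 rose and 0 fell by the scanner (median 1.96, adjusted p = 4.46e-09, adjusted p = 0.194 with an estimated correlation), and 13 rose and 1 fell by the table (median 1.11, adjusted p = 7.83e-05, adjusted p = 0.638 with an estimated correlation). Among cell death regulators Bcl2l1, a survival factor, rose 7.94-fold and 2.74-fold and Fas, a death receptor, 4.43-fold and 8.02-fold. In that list 8 of 19 rose and 1 fell by the scanner (median 0.53, adjusted p = 0.0106, adjusted p = 0.649 with an estimated correlation), and 8 rose and 0 fell by the table (median 0.94, adjusted p = 0.0211, adjusted p = 0.76 with an estimated correlation).

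Cell cycle genes fell at 6 h. Tk1, which makes thymidine phosphate for DNA synthesis, fell by 2.27 on the log2 scale (SE 0.052, n = 3 per group, adjusted p = 1.31e-10) in the scanner values and by 2.26 (SE 0.055) in the value table. Kif11, a mitotic motor, fell by 2.04 and by 1.11, the latter short of 2-fold without 0 h replicate 3 (-0.97). Of 24 cell cycle genes 17 fell and 0 rose by the scanner (median -1.35, adjusted p = 1.09e-06, adjusted p = 0.339 with an estimated correlation), and 12 fell and 0 rose by the table (median -0.99, adjusted p = 1.96e-09, adjusted p = 0.618 with an estimated correlation). Ccr2, the receptor that brings monocytes out of the marrow, fell 25-fold (-4.65 ± 0.14) and 16-fold (-4.0 ± 0.05). The lectin Clec10a fell 9.84-fold and 24.0-fold, and the organic anion carrier Slco2b1 at least 19.8-fold and 51.8-fold. Cyp2s1, a cytochrome P450, fell 39.6-fold by the scanner and stood at the lowest value in all 3 columns of the table. Hepacam2, an adhesion protein, fell 19.2-fold and 31.7-fold. Cd209a, the dendritic cell lectin DC-SIGN, fell at least 4.45-fold by the scanner and stood at the lowest value in 2 of 3 columns of the table.

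By limma 4799 of 18404 genes (26.1%) changed at 6 h in the scanner values, 1870 up and 2929 down, and 4608 (25%) in the value table, 2438 up and 2170 down. Called up in both were 1215 genes and down in both 1447, against 248 and 345 for independent calls, while 84 were called in opposite directions. Klrd1, a lectin-like receptor of natural killer cells, fell by 5.46 by the scanner and rose 2.09-fold by the table, where without 6 h replicate 1 it was short of 2-fold (log2 change 0.97), and Cx3cr1, the fractalkine receptor, fell by 1.58 and rose 20.8-fold. The median log2 change of all genes was -0.06 by the scanner and 0.14 by the table, and the changes printed are not corrected for it. With normexp background correction, whose offset shrinks the folds of dim genes by construction, 2576 scanner genes changed at 6 h. With quantile normalization, under which the columns at 0 h no longer hold ratios near 1, 2697 table genes changed. With the slide as a block the comparison rests on slide 1, the slide that holds both groups. It has 6 h replicate 1 as its only array at 6 h. A fit within slide 1 is therefore not a separate check, and the median log2 change of all genes was -0.07 in it.

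**Figure D1:**
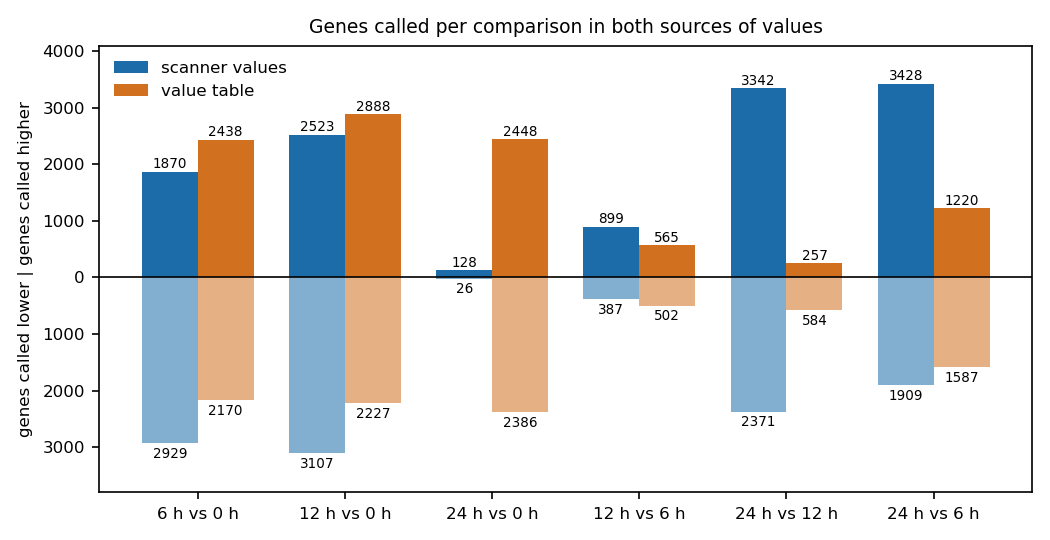
Number of genes called higher (full bars) and lower (pale bars) by limma in each of the 6 comparisons, for the scanner values (blue) and the value table (orange), of 18404 genes. At 24 h against 0 h the scanner values give 154 genes and the value table gives 4834.

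Exposure for 12 h was compared with 0 h to follow the response further. Nos2 rose at least 44.4-fold by the scanner and 9.78-fold by the table, and Il10 at least 134-fold and 7.08-fold. Il6 stood 727-fold (9.51 ± 0.063, n = 3 per group, limma adjusted p = 2.41e-13) and 76.1-fold above 0 h, Tnf 45.7-fold and 19.2-fold, Il1a 39.5-fold by the table with a log2 change of 8.78 by the scanner, and Il1b at least 18.9-fold and 18.3-fold. Cxcl1 stood 386-fold and 321-fold above 0 h, Cxcl5 26.2-fold by the scanner with a log2 change of 11.2 ± 0.16 in the table, and Ccl5 at least 17.0-fold and 27.4-fold. Ptgs2 rose at least 708-fold and 133-fold. Saa3 rose at least 351-fold on saturated arrays and by 10.1 ± 0.13 on the log2 scale of the table, and Marco, a scavenger receptor for particles and bacteria, rose 214-fold and 192-fold. Cytokine genes rose in 19 of 21 cases by the scanner (median 5.65, adjusted p = 1.32e-11, adjusted p = 0.188 with an estimated correlation) and 13 by the table with 1 fall (median 2.12, adjusted p = 0.000689, adjusted p = 0.618 with an estimated correlation). Chemokine genes rose in 15 of 20 with 1 fall (median 3.25, adjusted p = 3.67e-08, adjusted p = 0.194 with an estimated correlation) and in 13 with 3 falls (median 2.27, adjusted p = 0.0209, adjusted p = 0.705 with an estimated correlation). NF-kB targets rose in 21 of 21 (median 2.82, adjusted p = 7.63e-11, adjusted p = 0.194 with an estimated correlation) and in 17 (median 2.28, adjusted p = 2.31e-05, adjusted p = 0.618 with an estimated correlation).

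Maturation markers stood high at 12 h. Ccr7 was 10.8-fold (3.43 ± 0.073) and 9.05-fold above 0 h, Fscn1 14.3-fold and 15.3-fold, Cd83 4.89-fold and 7.50-fold, and Cd86 4.50-fold and 2.59-fold. Cd80 rose 12.5-fold by the scanner and did not pass by the table (-0.48 ± 0.12, adjusted p = 0.00422, under 2-fold). In the maturation list 15 of 16 genes rose and 1 fell by the scanner (median 2.52, adjusted p = 3.61e-07, adjusted p = 0.188 with an estimated correlation), and 9 rose and 0 fell by the table (median 1.05, adjusted p = 0.00167, adjusted p = 0.618 with an estimated correlation). MHC class I genes rose in 8 of 16 cases by the scanner and 7 by the table (medians 1.04 and 0.89, adjusted p = 0.000942 and 0.000689, adjusted p = 0.589 and 0.672 with an estimated correlation). Psmb9, a subunit of the immunoproteasome that trims peptides for MHC class I, rose 3.52-fold by the scanner and 1.46-fold, under the threshold, by the table. Casp4, the sensor of cytosolic lipopolysaccharide, rose 13.2-fold and 4.60-fold. The inflammasome list was called by the scanner (6 of 11 rose, median 1.05, adjusted p = 0.0188, adjusted p = 0.589 with an estimated correlation) and not by the table (4 rose, median 0.24, adjusted p = 0.561). At 6 h that list was called by neither, with 4 and 5 genes higher and 1 lower in each (adjusted p = 0.0733 and 0.0747).

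The interferon response stood apart between the sources at 12 h. Irf7, the factor that amplifies type I interferon, rose 22.8-fold (4.51 ± 0.071) by the scanner and 3.48-fold by the table, and Gbp2, a GTPase of host defence, 19.4-fold and 11.6-fold. Isg15 rose at least 17.3-fold and 5.77-fold, Rsad2 at least 23-fold and 32.0-fold, and Cxcl10 8.85-fold and 19.5-fold. Ifnb1 itself stood 4.49-fold and 20.4-fold above 0 h. All 27 measured interferon genes were called higher by the scanner (median 2.84, adjusted p = 1.64e-13, adjusted p = 0.194 with an estimated correlation), against 12 higher and 4 lower by the table (median 0.30, adjusted p = 0.879). GTPases rose in 10 of 10 (median 3.23, adjusted p = 9.14e-07, adjusted p = 0.188 with an estimated correlation) and in 5 of 10 (median 1.17, adjusted p = 0.0584). On source and time together the difference passed for both lists (adjusted p = 2.95e-17 and 1.55e-08), though neither passed with an estimated correlation (adjusted p = 0.186 for each).

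Proliferation genes were low at 12 h in both sources, with Kif11 down by 2.35 (SE 0.18) and by 2.54 (SE 0.13) on the log2 scale. Cell cycle genes fell in 15 of 24 cases by the scanner (median -1.36, adjusted p = 4.62e-06, adjusted p = 0.361 with an estimated correlation) and 20 of 24 by the table (median -1.79, adjusted p = 7.12e-13, adjusted p = 0.618 with an estimated correlation), and 0 rose. Ccr2 changed by -4.55 ± 0.14 and -5.40 ± 0.05. Clec10a fell 14.4-fold and 73.7-fold, Slco2b1 at least 24.1-fold and 21.2-fold, Cyp2s1 33.4-fold by the scanner and to the lowest table value in 2 of 3 columns, and Hepacam2 16.5-fold and 38.5-fold. Slc7a11 rose 7.30-fold and 47.0-fold, while Nqo1 was 38.3-fold higher by the table and did not pass by the scanner (0.56 ± 0.066). In the NRF2 list 6 of 17 rose by the scanner (median 0.62, adjusted p = 0.00324, adjusted p = 0.649 with an estimated correlation) and 13 by the table (median 2.92, adjusted p = 6.72e-07, adjusted p = 0.618 with an estimated correlation), and 0 fell. Hmgcs1 rose 3.19-fold by the table and did not pass by the scanner (0.62 ± 0.055). Cholesterol genes rose in 3 of 20 and fell in 2 by the scanner (median 0.21, adjusted p = 0.713), and rose in 13 by the table (median 1.21, adjusted p = 0.000347, adjusted p = 0.672 with an estimated correlation).

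Called at 12 h were 5630 genes (30.6%) in the scanner values, 2523 up and 3107 down, and 5115 (27.8%) in the value table, 2888 up and 2227 down, over a median of all genes of -0.03 and 0.22. Both sources called 1177 genes up and 1166 down, against 396 and 376 for independent calls, and 295 in opposite directions. Among the largest scanner rises were those of Nts, the gut peptide neurotensin, at least 1450-fold, and Il33, an alarm cytokine, at least 139-fold. In the table Nts rose 5.31-fold, and Il33 did not pass (-1.36 ± 1.6, and 1.16 without 0 h replicate 2). The table's call of Nts ended without 0 h replicate 1 (log2 change 1.80) or 2 (1.67) and without 12 h replicate 1 (2.46), 2 (2.30) or 3 (2.47). Lox, which cross-links collagen, rose at least 8.28-fold by the scanner and 293-fold by the table. Gsta3, a glutathione transferase, rose 226-fold by the table and did not pass by the scanner (-0.87 ± 0.069). No slide holds arrays of 0 and 12 h together. With the slide as a block 5517 genes changed, 4755 of them shared with the fit without it. With normexp 52.1% of the called genes were up, against 44.8% without it.

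**Figure D2:**
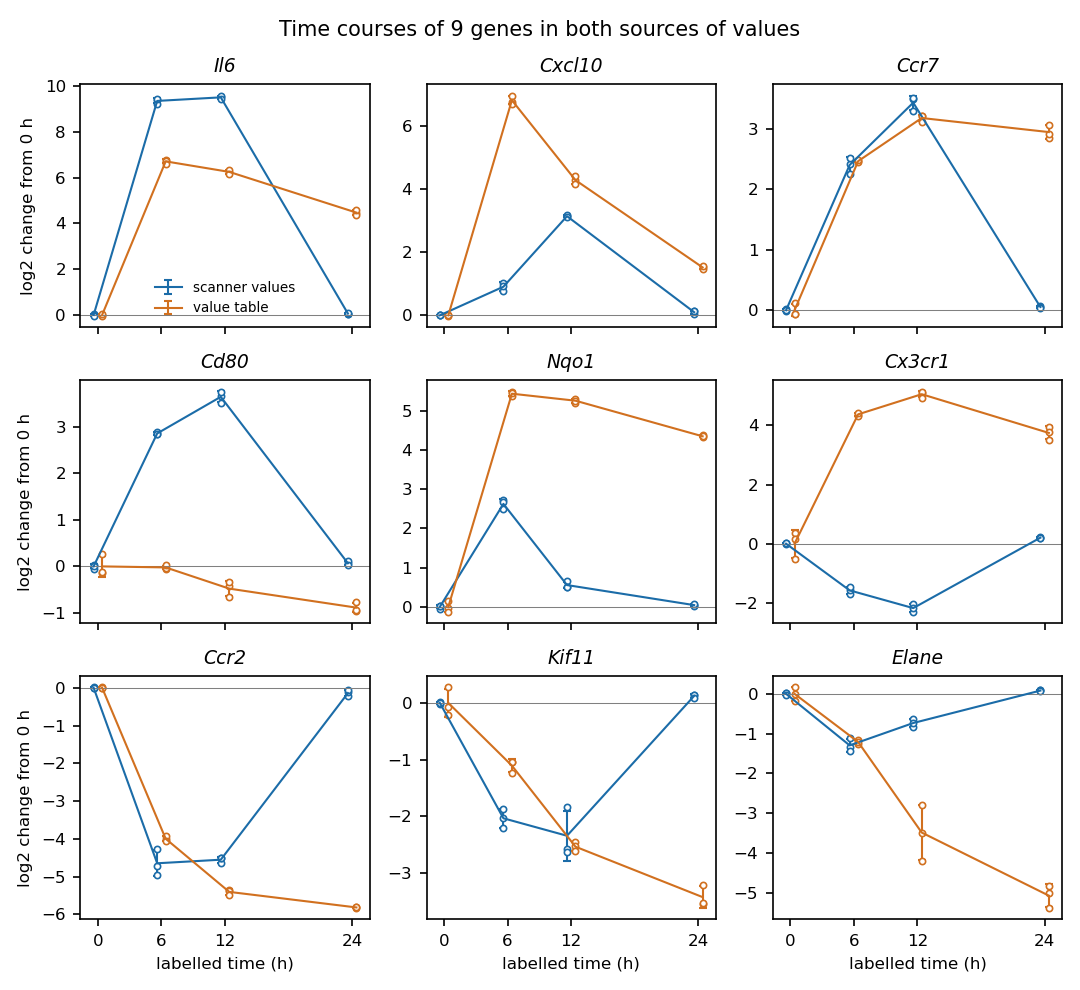
Log2 change from the mean at 0 h against the labelled time in hours for 9 genes, in the scanner values (blue) and the value table (orange). Open circles are the 3 replicates per time and lines with bars are means ± SD, and by the scanner the arrays labelled 24 h lie near 0 for Il6, Ccr7 and Kif11.

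The samples labelled 24 h were compared with 0 h to see what lasts for a day. In the value table Il6 stood 22.2-fold above 0 h (4.47 ± 0.07, n = 3 per group, limma adjusted p = 8.83e-12), Il1b 6.45-fold, Tnf 4.16-fold, Il10 3.65-fold and Ccl5 22.5-fold. Saa3 stood higher by 10.5 ± 0.13 and Cxcl5 by 10.4 ± 0.16 on the log2 scale, Marco 185-fold and Gsta3 382-fold. Lox rose by 8.87 ± 0.12, and Gpr162, an orphan receptor, 161-fold. Ccr7 stood 7.70-fold and Cd83 5.33-fold above 0 h, Ifnb1 9.36-fold, Cxcl10 2.87-fold, Ptgs2 23.8-fold, Nos2 2.35-fold and Traf1 13.4-fold. In the same table Ccr2 fell by 5.81 (SE 0.05), Kif11 by 3.43 (SE 0.13) and Top2a, a topoisomerase of dividing cells, by 3.11 (SE 0.079). Fcrls, an Fc receptor-like protein, fell 63.0-fold, Clec4f, a lectin, 87.7-fold, and Cish, a feedback inhibitor of cytokine signals, 59.7-fold. By the scanner none of the genes named in this comparison so far passed the limma threshold on arrays labelled 24 h. There Il6 was at 0.06 ± 0.063 (adjusted p = 0.654), Tnf at 0.04 ± 0.053, Ccr7 at 0.05 ± 0.073, Ccr2 at -0.14 ± 0.14 and Kif11 at 0.12 ± 0.18. Values of Cd80 and Cd86 at 24 h are not given, so the maturation markers named here are only part of the fixed ones.

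Among values of the table, 4834 genes (26.3%) changed at 24 h, 2448 up and 2386 down, over a median of all genes of 0.12. In the scanner values 154 (0.837%) changed, 128 up and 26 down, with 658 at an adjusted p under 0.05 of any size and 3736 at an unadjusted p under it. Called in both sources were 12 genes up and 0 down, against 17 and 3 for independent calls, and 41 were called opposite ways. The scanner count rested on single arrays. Without 0 h replicates 1, 2 and 3 it was 48, 46 and 38, without 24 h replicates 1, 2 and 3 it was 38, 24 and 29, and without 12 h replicate 3 it was 292. No slide holds arrays of both times, and with the slide as a block it was 23, of which 2 were among the 154. Among the 154 were Kank1, an adaptor of the cell cortex, with a rise of at least 3.26-fold, and Zfp317, a zinc finger protein, with a fall by 1.78 (SE 0.16). With the slide as a block neither of these passed. The scanner call of Kank1 ended without 24 h replicate 2 (3.24). In the table Kank1 fell by 2.01, and Zfp317 did not pass (0.23 ± 0.084).

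Lists at 24 h followed the same division. By the table cytokines stood higher in 11 of 21 cases with 1 lower (median 1.85, adjusted p = 0.000646), NF-kB targets in 13 of 21 with 2 lower (median 1.39, adjusted p = 0.000917), effector products in 12 of 20 with 3 lower (median 1.45, adjusted p = 0.00728), NRF2 genes in 13 of 17 (median 2.28, adjusted p = 4.79e-07) and cholesterol genes in 11 of 20 (median 1.05, adjusted p = 0.000134). With an estimated correlation the adjusted p of these 5 lists was 0.618, 0.672, 0.672, 0.618 and 0.638 in that order. MHC class I genes were higher in 4 of 16 cases (median 0.54, adjusted p = 0.0209, adjusted p = 0.76 with an estimated correlation) and mitochondrial genes in 2 of 27 (median 0.38, adjusted p = 0.0211, adjusted p = 0.889 with an estimated correlation). Nqo1 stood 20.4-fold, Slc7a11 30.2-fold and Hmgcs1 2.65-fold above 0 h. Of 24 cell cycle genes 22 fell (median -2.43, adjusted p = 7.12e-13, adjusted p = 0.618 with an estimated correlation). Elane and Mpo, enzymes of granulocyte precursors, changed by -5.08 ± 0.29 and -4.45 ± 0.097, and 11 of 14 neutrophil and granulocyte precursor genes fell (median -1.96, adjusted p = 0.000216, adjusted p = 0.618 with an estimated correlation). Cpa3, a mast cell protease, fell by 2.30 (SE 0.088), with 6 of 7 mast cell and basophil genes lower and 1 higher (median -1.13, adjusted p = 0.00378, adjusted p = 0.618 with an estimated correlation). Prg2, the major basic protein of eosinophils, fell by 5.85 (SE 0.12). Macrophage markers fell in 6 of 12 cases and rose in 2 (median -0.87, adjusted p = 0.0397, adjusted p = 0.735 with an estimated correlation). By the scanner the GTPases were the sole list of 29 called (0 of 10 members passed with limma, median 0.16, adjusted p = 0.00145, adjusted p = 0.339 with an estimated correlation). The maturation, chemokine and interferon lists were called by neither source at 24 h. Over all 87 tests camera called 32 by the scanner and 37 by the table, and with an estimated correlation 0, with a lowest adjusted p of 0.188 and 0.618, while fry called 60 and 76.

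**Figure D3:**
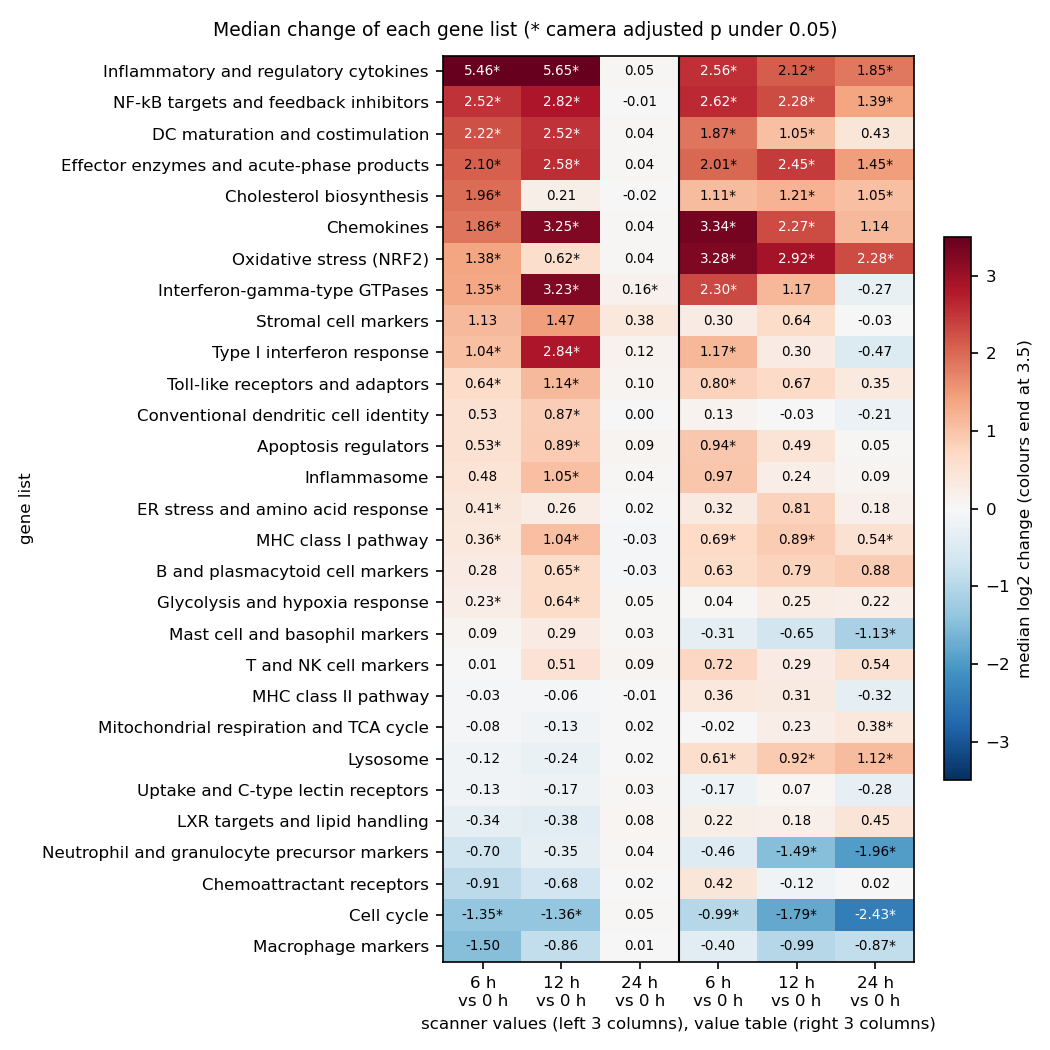
Median log2 change of 29 gene lists against 0 h at 6, 12 and 24 h in the scanner values and the value table, with colours ending at 3.5 in either direction. An asterisk marks a camera adjusted p under 0.05, as for 15, 16 and 1 lists by the scanner and 14, 11 and 12 by the table.

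Further metabolic lists were examined at 6 and 12 h. Pfkfb3, which speeds glycolysis, rose 2.42-fold (1.27 ± 0.054, n = 3 per group) and 2.79-fold at 6 h and 7.44-fold and 7.04-fold at 12 h, while Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.38 and 2.49 at 6 h, short of the threshold under normexp by the scanner. Of 23 glycolysis and hypoxia genes 5 rose and 1 fell by the scanner at 6 h (median 0.23, adjusted p = 0.00703, adjusted p = 0.649 with an estimated correlation) and 8 rose and 0 fell at 12 h (median 0.64, adjusted p = 0.000196, adjusted p = 0.589 with an estimated correlation). By the table, 2 rose and 4 fell at 6 h, where the median was 0.04, the mean -0.23 and the test's direction down (adjusted p = 0.262), and 3 rose and 2 fell at 12 h (median 0.25, adjusted p = 0.98). The difference between sources at 12 h passed (adjusted p = 0.000129, adjusted p = 0.415 with an estimated correlation). Asns, which makes asparagine, rose 2.26-fold and 2.64-fold at 6 h, though under quantile normalization neither reached 2-fold. Sesn2, a stress sensor, fell by 1.32 and 1.01, the latter just short of 2-fold without 0 h replicate 3 (-1.0) or 6 h replicate 2 (-0.99). In the ER stress and amino acid list 5 of 19 rose and 1 fell by the scanner (median 0.41, adjusted p = 0.0388, adjusted p = 0.725 with an estimated correlation), and 8 rose and 3 fell by the table (median 0.32, adjusted p = 0.371). Fabp4, a fatty acid carrier, rose 11-fold and 6.07-fold, and Pparg, a lipid-sensing receptor, fell by 1.97 and 1.12. Nr1h3, the oxysterol receptor LXR alpha, rose 2.32-fold and 11.5-fold at 12 h, and under normexp the first no longer passed. Of 17 LXR and lipid genes 1 rose and 3 fell by the scanner at 6 h (median -0.34, adjusted p = 0.528), and 5 rose and 1 fell by the table (median 0.22, adjusted p = 0.897). Fh1, an enzyme of the citric acid cycle, fell by 1.19 and 1.12. The mitochondrial list was not called at 6 h, with 2 of 27 higher and 2 lower by the scanner (median -0.08) and 0 and 1 by the table (median -0.02).

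Lysosomal genes went apart. Lipa, the acid lipase, fell by 1.70 (SE 0.065, n = 3 per group, limma adjusted p = 3.3e-09) at 12 h by the scanner and rose 3.81-fold by the table. At 24 h the table held Ctsk, a cathepsin, 29.9-fold, Gpnmb, a membrane glycoprotein of lysosomes, 8.61-fold and Lgmn, a protease, 3.55-fold above 0 h, and none of these passed by the scanner. Of 24 lysosomal genes 8, 12 and 14 rose at 6, 12 and 24 h by the table (medians 0.61, 0.92 and 1.12, adjusted p = 0.000134, 4.43e-06 and 4.04e-08), and 0 fell. With an estimated correlation the adjusted p was 0.672, 0.618 and 0.618. By the scanner 0 rose and 2, 4 and 0 fell (medians -0.12, -0.24 and 0.02, adjusted p = 0.52, 0.136 and 0.98). The difference between sources passed at 6 h (adjusted p = 1.45e-08, adjusted p = 0.288 with an estimated correlation). H2-DMa, which loads peptides on MHC class II, fell by 1.92 and 1.79 at 6 h and by 1.85 and 2.08 at 12 h. In the MHC class II list 0 of 14 rose and 4 fell by the scanner at 6 h (median -0.03, adjusted p = 0.52), and 1 rose and 2 fell by the table (median 0.36, adjusted p = 0.581). Marco rose 176-fold and 97.9-fold at 6 h and Clec4e, a lectin that senses mycobacterial lipid, at least 6.88-fold and 73.9-fold. The list of uptake and lectin receptors moved both ways, with 4 of 23 higher and 6 lower by the scanner (median -0.13, mean 0.06, direction down, adjusted p = 0.776). By the table, 8 were higher and 7 lower (median -0.17, mean 0.05, direction down, adjusted p = 0.637).

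Receptors and lineage markers gave mixed lists. Fpr1, a receptor for bacterial peptides, rose 5.34-fold (2.42 ± 0.038, n = 3 per group) and 11.5-fold at 6 h, and Cxcr2, a neutrophil chemokine receptor, fell by 2.27 and 3.07. Of 15 chemoattractant receptors 4 rose and 7 fell by the scanner (median -0.91, adjusted p = 0.354), and 6 rose and 6 fell by the table (median 0.42, adjusted p = 0.98). Irf8, a factor of dendritic cell lineages, rose 3.00-fold and 2.03-fold at 6 h and 4.46-fold and 3.33-fold at 12 h, and the table's value at 6 h did not pass under quantile normalization or without 0 h replicate 2 (log2 change 0.98) or 6 h replicate 1 (0.99). Irf4, a further lineage factor, rose 3.45-fold by the scanner at 12 h and fell by 2.38 by the table. The list of conventional dendritic cell identity was called at 12 h by the scanner, with 7 of 15 higher and 2 lower (median 0.87, adjusted p = 0.0394, adjusted p = 0.649 with an estimated correlation), and not by the table, with 3 and 2 (median -0.03, adjusted p = 0.455). C1qb, a complement protein of macrophages, fell by 1.22 and 1.59 at 12 h, and Fcgr1, an Fc receptor, rose 3.26-fold and fell by 2.77. Macrophage markers fell in 7 of 12 cases and rose in 1 at 6 h by the scanner (median -1.50, adjusted p = 0.122). By the table, 3 rose and 2 fell, with a median of -0.40, a mean of 0.40 and a direction down (adjusted p = 0.486).

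Markers of other lineages were examined at 6 and 12 h. Elane fell by 1.30 and 1.21 at 6 h, the first short of the threshold under normexp, and by the table by 3.49 (SE 0.29, n = 3 per group) at 12 h, where the scanner did not pass it (-0.74 ± 0.08). Granulocyte precursor genes fell in 8 of 14 cases and rose in 1 at 12 h by the table (median -1.49, adjusted p = 0.00478, adjusted p = 0.618 with an estimated correlation), against 3 and 1 by the scanner (median -0.35, adjusted p = 0.375). Lck, a kinase of T cells, rose 7.04-fold and 3.30-fold at 12 h, and Cd3d, a part of the T-cell receptor, fell by 2.50 and 1.60. Of 13 T and NK cell markers 3 rose and 4 fell at 6 h by the scanner (median 0.01, mean -0.34, direction down, adjusted p = 0.946), and 5 rose and 3 fell by the table (median 0.72, adjusted p = 0.801). Blnk, an adaptor of B cells, rose 3.19-fold and 3.83-fold at 12 h. The B and plasmacytoid list was called by the scanner, with 4 of 10 higher and 1 lower (median 0.65, adjusted p = 0.0438, adjusted p = 0.648 with an estimated correlation), and not by the table, with 4 higher (median 0.79, adjusted p = 0.262). Dcn, a stromal proteoglycan, rose at least 2.59-fold and 11.1-fold at 12 h, the first short of the threshold under normexp. Of 6 stromal markers 3 rose by the scanner at 6 h (median 1.13, adjusted p = 0.0901) and 1 rose and 1 fell by the table (median 0.30, adjusted p = 0.582). Car2, a carbonic anhydrase, rose 9.07-fold and 5.35-fold at 6 h, alone among the 4 measured erythroid markers in either source, too few for a test. At 6 h mast cell and basophil markers rose in 1 of 7 cases by the scanner (median 0.09, adjusted p = 0.528). By the table, 2 rose and 1 fell, with a median of -0.31, a mean of 0.32 and a direction down (adjusted p = 0.736). Median, mean and test differed in sign in 13 of the scanner's list tests, 10 of them at 24 h, and in 10 of the table's, none of which camera called.

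From 6 to 12 h the sources moved apart. Cxcl10 rose 4.72-fold (2.24 ± 0.062, n = 3 per group, limma adjusted p = 2.39e-09) in the scanner values and fell by 2.54 (SE 0.077) in the value table. Slfn4, an interferon-induced gene of myeloid cells, rose 13.6-fold and fell by 1.15 (SE 0.12), and Ly6a, a surface marker that interferon raises, rose 12.4-fold and did not pass (0.55 ± 0.15). Ppbp, a neutrophil-attracting chemokine, fell by 3.04 and 1.07. Clu, a secreted chaperone, rose 15.2-fold by the table alone. Antxr1, a collagen receptor, rose 2.69-fold and 14.5-fold, and Col16a1, a collagen, fell 2.51-fold and 10.9-fold. Neither scanner value of Antxr1 and Col16a1 passed under normexp, nor did that of Col16a1 with the slide as a block. The interferon list had a median of 1.83 by the scanner, with 26 of 27 higher, and -1.04 by the table, with 15 of 27 lower, and the difference passed (adjusted p = 9.52e-28, adjusted p = 0.0425 with an estimated correlation). Cholesterol genes fell in 18 of 20 cases by the scanner (median -1.94), against 1 rise and 0 falls by the table (median 0.096, adjusted p of the difference 1.93e-15, adjusted p = 0.0425 with an estimated correlation). Called were 1286 genes, 899 up and 387 down, by the scanner and 1067, 565 up and 502 down, by the table. In both 57 rose and 19 fell, against 28 and 11 for independent calls, 152 went opposite ways, and r across genes was -0.14. Within slide 2, which holds both times, 1354 scanner genes changed.

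From 12 h to samples labelled 24 h some genes fell in both sources. Cxcl9, an interferon-gamma-induced chemokine, fell by 4.14 (SE 0.045, n = 3 per group, limma adjusted p = 1.44e-12) by the scanner and 4.49 (SE 0.24) by the table. Il6 fell 697-fold and 3.43-fold, Ptgs2 at least 888-fold and 5.56-fold, and Il1f6, an interleukin 36, at least 152-fold and 10.7-fold. Nts fell at least 2100-fold by the scanner and did not pass by the table (-1.61 ± 0.91), where it did without 0 h replicate 3. Smim5, a small membrane protein, rose 35.1-fold by the scanner and fell by 3.51 by the table. Arg1, which splits arginine, and Cdkn1c, a brake on cell division, rose 8.76-fold and 6.94-fold by the table alone. Called were 5713 genes, 3342 up and 2371 down, by the scanner, over a median of 0.11, and 841 by the table, 257 up and 584 down, over a median of -0.13. In both 150 rose and 311 fell, against 47 and 75 for independent calls, and 105 went opposite ways. Slide 3 holds both times, with 12 h replicate 3 as its only array at 12 h, and within it the scanner median of all genes was 0.04. With normexp 49% of the genes called by the scanner were up, against 58.5% without it.

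Between 6 h and samples labelled 24 h Il6 fell by 9.29 (SE 0.063, n = 3 per group, limma adjusted p = 2.19e-13) by the scanner and 2.24 (SE 0.07) by the table, and Tnf changed by -5.88 and -3.16. Cxcl10 fell by 5.31 by the table and did not pass by the scanner (-0.81 ± 0.062). Ccr7 fell by 2.35 by the scanner and did not pass by the table (0.48 ± 0.069). Interferon genes were lower in 12 of 27 cases by the scanner and 20 of 27 by the table. Cell cycle genes were higher in 18 of 24 cases by the scanner and lower in 12 of 24 by the table. Called were 5337 genes, 3428 up and 1909 down, over a median of 0.15 by the scanner, and 2807, 1220 up and 1587 down, by the table. In both 639 rose and 463 fell, against 227 and 165 for independent calls, and 537 went opposite ways. No slide holds both times, and with the slide as a block 4733 scanner genes changed. By the table, 2606 then changed, 1425 up and 1181 down, so that the larger share was up. The slides are those of the scanner arrays, and whether they hold for the table's columns is not known.

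Over the time course as a whole 6647 genes (36.1%) changed by the scanner and 6784 (36.9%) by the table. These passed limma's F-test and also changed at least 2-fold against 0 h at some time. By adjusted p of the F-test alone 15660 scanner genes passed. Of 1870 genes up at 6 h by the scanner 1630 were lower on arrays labelled 24 h than at 6 h and 0 were higher, and of 2929 genes down at 6 h 2778 were higher and 0 lower. By the table, 522 of 2438 were lower and 165 higher, and of 2170 genes down 445 were higher and 271 lower. As both comparisons share the arrays at 6 h, noise alone would favour a return. In data simulated with the 6 h change kept at 12 and 24 h, 4981 and 4796 genes were called at 6 h and 0 of them returned. No simulated gene differed between 6 and 24 h, so the adjusted threshold was stricter there. In the real data 5337 and 2807 genes were called between these times. The simulation therefore cannot show how many returns noise would give. Independent calls would give 194 and 546 returning genes by the scanner and 210 and 144 by the table.

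Some calls of named genes depended on the scaling. Normexp ended the scanner calls of Cd209a, Cx3cr1, Elane and Pdk1 at 6 h and of Cx3cr1, Dcn and Nr1h3 at 12 h. Quantile normalization of the table ended those of Csf2, Kif11, Klrd1, Elane, Bcl2l1, Asns, Sesn2 and Irf8 at 6 h, and those of Cd86, Nts, Lck, Dcn and Irf7 at 12 h. It also ended those of Nos2, Tlr2 and Lgmn at 24 h, of Il1f6 and Cdkn1c from 12 to 24 h, and of Slfn4 and Ppbp from 6 to 12 h, while the direction of every one of these stayed as it was.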

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

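The tests of the sources against each other, of the markers and of the genes called between arrays labelled 24 h and 0 h were chosen after those results were seen, as were the fits of the value table with their counts over other splits, whereas those counts for the scanner values were fixed beforehand.

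Ccr7, Il6 and Kif11 show how the sources part. At 24 h Ccr7 stood at 0.05 ± 0.073 in the scanner values and 2.94 ± 0.069 in the value table, Il6 at 0.06 and 4.47, and Kif11 at 0.12 and -3.43. Both sources were put in a single limma fit that did not pair the samples. In it the effect of time differed between them for 2774 genes at 6 h, 5492 at 12 h and 5151 at 24 h, each against 0 h. Of these, 1892, 3470 and 2377 lay higher in the table and 882, 2022 and 2774 lower. Among 29 gene lists camera found a difference for 11 at 6 h, 14 at 12 h, 12 at 24 h and 18 between 12 and 6 h. With an estimated correlation 0 passed for the first 3 comparisons (lowest adjusted p = 0.186) and 3 for the last, namely type I interferon genes, interferon-gamma-type GTPases and cholesterol genes (adjusted p = 0.0425). Cytokines at 6 h had medians of 5.46 and 2.56 (adjusted p of the difference 1.97e-08), and cell cycle genes at 24 h 0.04 and -2.43 (1.71e-14), with an adjusted p of 0.186 and 0.186 under an estimated correlation.

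Arrays labelled 24 h lie with those at 0 h in the scanner values and apart from them in the value table. The tables argue against labels exchanged among the scanner arrays as the whole cause. In a score over 2768 genes that the table calls the same way at 6, 12 and 24 h, 3 columns of the table lay below the widest gap (2.06, the next being 0.112). As the table's own calls picked these genes, its number was set by that choice and only the scanner's is an observation. In the scanner values 6 arrays lay below the widest gap (1.3, the next being 0.0469). An exchange within the series leaves the number of arrays below the gap as it is. Correlations of the changes across genes do not decide whether labels were exchanged. The highest of a scanner change with the table's 24 h change was 0.49, against 0.73 and 0.54 for equal labels at 6 and 12 h. The scanner's 12 h change and the table's 6 h change gave 0.64, above the value for equal labels at 12 h. The labels of 12 h are thus also in doubt between the sources. The median correlation of a sample's own deviation between the sources was 0.08, and 0.754 for an array under 2 background corrections, which is consistent with values from different hybridisations. Of the 12 arrays 8 correlated more highly with another column than with their own, up to 0.394 for 12 h replicate 2 with the column of 0 h replicate 1, below the lowest value of 0.48 under 2 corrections, and what they share was not tested. Whether expression was back at the 0 h level by 24 h cannot be told apart from arrays of cells other than those labelled, because the table calls 4834 genes at that time and nothing in the files shows which source holds the 24 h cultures. A swap with samples outside the series stays open, as does an end of the response by 24 h.

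The 154 genes called between arrays labelled 24 h and 0 h by the scanner were mostly dim. Kank1 rose at least 3.26-fold, and 25 of the 87 with a symbol were olfactory receptor genes, such as Olfr649 at 2.29 ± 0.37 (adjusted p = 0.0192, a bound of 1.53-fold), a receptor of odours. Its call ended without 0 h replicate 1 or 2 or any single 24 h replicate (2.11 to 2.43). Of the 154, 130 (84.4%) lay among the dimmest 25% of genes at 0 h, and 105 were not well above background on all arrays at 0 h, which is consistent with signal near the background. The count of 154 was 38, 24 and 29 without 24 h replicates 1, 2 and 3, 48, 46 and 38 without 0 h replicates 1, 2 and 3, and 292 without 12 h replicate 3. With the slide as a block 32.9% of the median log2 difference was left, 0.50 of 1.52 with the median SE going from 0.27 to 0.47, and 29 genes changed sign. A difference between slides would give this. Genes picked for a large difference on the same arrays would also shrink in any noisier estimate, so it does not decide. The calls ended both because the differences shrank and because the SE grew, no slide holds both groups, and a response of the cells stays open as untested.

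Other splits of the same arrays were counted for every comparison. For the time course by the scanner 6647 genes changed, and 1 of 100 splits, the real one, gave as many, the highest other giving 5964. In the value table the number was 6784, with 1 of 100 and a highest other of 5471. Both shares lie under 0.05, the limit set for chance, and are the lowest that 100 splits can give. As times and slides partly coincide on the scanner arrays, such splits cannot separate time from slide. The number of lists called, 32 by the scanner, was reached in 26 of 100 splits, the highest other giving 44, and 37 by the table in 9 of 100, the highest other giving 49, so chance cannot be excluded for these numbers. For 3 arrays against 3, 10 splits are too few for a share under 0.05. The real and highest other scanner counts were 4799 and 0 at 6 h, 5630 and 0 at 12 h, 154 and 0 at 24 h, each against 0 h. They were 1286 and 27 for 12 h against 6 h, 5713 and 4 for 24 h against 12 h, and 5337 and 0 for 24 h against 6 h. In the same order the counts by the value table were 4608 and 1, 5115 and 0, 4834 and 0, 1067 and 6, 841 and 8, and 2807 and 1.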

How the results depend on the processing

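Settings tried on the value table itself and contrasts within a slide were chosen after the data were seen, and the others, among them the table in place of the scanner values, beforehand. The cause of a change was not tested unless it is named.

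By the scanner the 6, 12, 12 to 6, 12 to 24 and 6 to 24 h counts and the time course stayed within 1.5 times under quantile normalization, median scaling, no filter, single or averaged probes, either block, a variance trend and a threshold of 0.01, and so did those 5 counts with the 2 groups alone, which leaves no time course. With normexp, whose offset shrinks dim folds by construction, 2576, 3063 and 8 genes changed at 6, 12 and 24 h against 0 h. It gave 577 for 12 h against 6 h, 3154 for 24 h against 12 h, 2699 for 24 h against 6 h and 3571 over the time course. Of the 8 genes at 24 h, 25% were up, against 83.1% of 154. At 12 h 52.1% were up against 44.8%, from 12 to 24 h 49% against 58.5%, and from 6 to 24 h 53.4% against 64.2%. By adjusted p alone, a wider threshold by construction, the same 7 counts were 13206, 13918, 658, 8733, 13838, 13725 and 15660. A filter over all arrays tests fewer genes and gave 47 at 24 h, 806 for 12 h against 6 h and 3488 for 24 h against 6 h. The count at 24 h against 0 h was 96 without a filter, 244 with a variance trend, 17 at an adjusted p under 0.01 and 392 with the 2 groups alone. With the slide as a block it was 23, of which 39.1% were up, and 2 were shared with the 154. With the replicate number as a block it was 86, 82 of them shared. The labels do not say whether equal numbers mark the same experiment. Residuals of equal numbers correlated at -0.09 to 0.16 by the scanner and -0.08 to 0.23 by the table, so little pairing was seen. The value table gave 4834 for 24 h against 0 h, 841 for 24 h against 12 h and 2807 for 24 h against 6 h.

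With each array left out the scanner counts ranged from 4735 to 4930 at 6 h, 5594 to 5672 at 12 h and 24 to 292 at 24 h, each against 0 h. They were 1263 to 1375, 5508 to 5997 and 5203 to 5394 for 12 h against 6 h, 24 h against 12 h and 24 h against 6 h, and 6528 to 6744 over the time course. At 24 h the count was 48, 46 and 38 without 0 h replicates 1, 2 and 3, 38, 24 and 29 without 24 h replicates 1, 2 and 3, and 292 without 12 h replicate 3. The table's counts moved within 1.5 times, though the share up fell below 50% at 24 h without 0 h replicate 2 (49.7%) or 24 h replicate 3 (49.6%), against 50.6%, and from 6 to 12 h without 6 h replicate 3 (48.9%) or 12 h replicate 2 (48.1%), against 53%. It was 49.8% at 24 h without a filter, and 54.7% from 6 to 24 h with the slide as a block, against 43.5%. That block uses the slides of the scanner arrays, which may not be those of the table's columns. With quantile normalization, under which the columns at 0 h no longer hold ratios near 1, the table gave 2697, 2661, 2637, 185, 110 and 1126 in the order of the comparisons above and 3360 over the time course. Up were 41% at 6 h against 52.9%, 43.3% at 12 h against 56.5%, 43.5% at 24 h against 50.6%, 41.8% from 12 to 24 h against 30.6% and 55.8% from 6 to 24 h against 43.5%. Lists called numbered 0 with an estimated correlation in either source, and 60 and 76 by fry, which compares a list with no other genes. Leaving out arrays gave 30 to 34 lists by the scanner.

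Of 190 named scanner values 118 kept direction and side of the threshold in the value table, 6 lost and 34 gained a call, and 32 reversed. Of the 32, 11 were called in both sources, 6 by the scanner alone and 15 by the table alone, where 14 of the scanner values lay within 0.5 of 0, so that their sign says little. At 6 h the table held Cd80 at -0.022, Klrd1 at 1.06, Cx3cr1 at 4.38 and Osm at -1.78. At 12 h it held Cd80 at -0.48, Cx3cr1 at 5.06, Il33 at -1.36, Gsta3 at 7.82, Lipa at 1.93, Irf4 at -2.38 and Fcgr1 at -2.77. At 24 h it held Cxcl5 at 10.4, Ccl5 at 4.49, Ptgs2 at 4.58, Nos2 at 1.24, Hmgcs1 at 1.40, Traf1 at 3.75, Kif11 at -3.43, Lox at 8.87, Clec4f at -6.45, Prg2 at -5.85, Elane at -5.08 and Mpo at -4.45. The others at 24 h were Cpa3 at -2.30, Gpnmb at 3.11, Kank1 at -2.01, Zfp317 at 0.23 and Olfr15 at -1.50. Smim5 was at -3.51 from 12 to 24 h, Ccr7 at 0.48 from 6 to 24 h, and Cxcl10 and Slfn4 at -2.54 and -1.15 from 6 to 12 h. With the slide as a block 183 values were the same, 5 lost and 2 gained a call. In the table Il33 at 12 h ranged from -2.66 to 1.16 over the arrays left out, the latter without 0 h replicate 2. Of 2280 scanner values with an array left out 2268 kept direction and side, and 12 lost a call. Normexp ended 12 calls, and 20 ended with quantile normalization of the table. Signal over background limits the dim genes, as 50.9% to 59.6% of spots were well above it.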

Other observations

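The tests of the marker genes and the fits of the value table were chosen after the results were seen, and the slide as a block beforehand.

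Granulocyte precursor and mast cell genes fell together in the value table at 24 h. Elane and Mpo, enzymes stored in the granules of neutrophil precursors, changed by -5.08 ± 0.29 and -4.45 ± 0.097 on the log2 scale, with n = 3 per group. Cpa3, a protease of mast cells, changed by -2.30 ± 0.088, and Prg2, a granule protein of eosinophils, by -5.85 ± 0.12. The culture was started from whole marrow and harvested with no sort named in the labels, so a few such cells may be in it. In the scanner values none of these 4 genes passed with limma on arrays labelled 24 h (0.08 ± 0.08, 0.10 ± 0.049, 0.03 ± 0.22 and 0.19 ± 0.032), and Cpa3 stood at 1.18, past the threshold, with the slide as a block. Over both marker lists 17 of 21 members were lower in the table and 1 higher. Of the 21, 2 stand in another list as well. A common scaling factor per column is argued against, as the median of all genes was 0.12 and that of the members -1.41. Other forms of scaling between columns would not have to move the median of all genes, and they stay open. A signal near the background stays open. By the scanner 4.76% of the members, 1 of 21, were not well above background on all arrays at 0 h, but the filter favours a low share and the table holds no such flags. Fewer such cells and fewer transcripts per cell cannot be told apart, because a fall in bulk RNA has the same sign under either. As the sources part at 24 h, the fall holds for the value table alone.

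Of the receptor genes, Tlr2 stood 2.03-fold and Cd14, the co-receptor, 3.93-fold above 0 h in the value table at 24 h, and Tlr4 did not pass (0.20 ± 0.069). Tlr2 did not reach 2-fold under quantile normalization or without 0 h replicate 2 (log2 change 0.99). At 12 h Tlr2 stood 3.49-fold higher by the table and short of the threshold by the scanner (0.85 ± 0.045), and Myd88 4.23-fold by the scanner and short of it by the table (0.26 ± 0.069). Cd14 passed in both, at least 2.78-fold and 4.81-fold. Mgl2, a lectin of dendritic cells and macrophages, fell by 6.67 by the table at 24 h, with 1 of its values at the lowest ratio. Olfr15, an olfactory receptor gene, rose at least 1.31-fold on arrays labelled 24 h and did not pass by the table (-1.50 ± 0.93), where it did without 6 h replicate 2. Its scanner call ended without any single array at 0 or 24 h (2.03 to 2.45).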
